A study of Mus musculus with 12 samples.

How the data were processed

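RNA was measured in 12 samples of E14 mouse embryonic stem cells. The cells were wild type (WT) or carried a knockout of Mettl3 (KO), the catalytic subunit of the enzyme complex that places N6-methyladenosine (m6A) on messenger RNA. They were grown in serum and LIF (called FBS here) or were paused for 2 weeks with INK128 at 200 nM. INK128 is a kinase inhibitor of mTOR, the master regulator of growth and protein synthesis. Each of the 4 groups held 3 samples. Per the labels' protocols, 200000 cells were lysed per sample, 2 µl of ERCC Mix 1 (a set of synthetic RNAs of known amounts) at a dilution of 1 in 100 was added to 10 µl of RNA, and stranded libraries were made from polyadenylated RNA. Because the RNA came from equal numbers of cells, the ratio of cellular to ERCC counts was taken as RNA per cell. The spike-in went into the RNA and not into the cells, so the ratio does not correct for losses before that step.

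The authors deposited a table of raw read counts per gene symbol with 92 ERCC rows and 24421 gene rows. They also deposited log2 values that they describe as normalized to cell number. For the 3384 genes with at least 500 counts, the deposited log2 values equalled the log2 of the count plus 0.5 plus one constant per sample, with a largest SD of 6.6e-10. The submitters' processing notes name Trim Galore 0.4.0, featureCounts, Subread 1.5.0, edgeR 3.32.1 and the mouse build mm10, without saying what each was used for. The aligner, the gene annotation and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands, and of near-identical copies, may be counted for either gene.

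The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. All 12 samples entered a fit of 4 group means with robust quasi-likelihood dispersions, and p-values were adjusted by Benjamini and Hochberg (BH) with a threshold of 0.05. Genes were kept with the default filter on counts (minimum count 10, minimum total 15), which left 15281 genes. Every comparison was made on 2 scales. On the per-cell scale the library size was the ERCC total multiplied by a TMM factor computed over the ERCC rows. Its error is shared by all genes of a library, so per-cell calls of different genes are not independent. On the relative scale it was the total of the genes multiplied by a TMM factor computed over the genes, so a change is measured against the typical gene. RNA per cell was the log2 ratio of cellular to ERCC counts, compared with exact two-sided permutation tests. With 3 samples against 3 such an exact test cannot go below p = 0.1, and the difference between both pausing effects was tested over 400 arrangements of the genotypes within conditions. CPM in the text are TMM-scaled, given as mean ± SD with n = 3 per group, and log2 fold changes are given ± SE. The fitted log2 fold change of a gene with 10 or fewer counts over the 3 libraries of a group depends on the prior count, so the text gives the ratio of CPM-scaled counts instead, with a 95% interval. Where a group had 0 counts, a lower bound was set with a floor of 3 counts over the group. These intervals and floors cover counting error only.

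Lists of genes were fixed before the data were examined, and 31 of them had members that could be tested. The lists of mitochondrial-encoded messages and of the two-cell-like state had too few members among the tested genes and were not analysed here. Each list was tested against all other genes with camera (limma 3.58.1) on TMM-scaled log2 CPM (prior count 2) with a preset correlation between genes of 0.01. The test was repeated with an estimated correlation and with ERCC scaling, and adjusted over the lists of a comparison. The genes named in the text follow a rule that was also fixed before the data were examined. It takes Mettl3, Mettl14, Mycn, Myc, Pou5f1, Sox2, Nanog and Eif4ebp1 always. Per comparison it adds the 6 highest and the 6 lowest fold changes among called genes with at least 5 CPM in the higher group. In the 4 comparisons of 2 groups their replicates must also not overlap, and predicted or clone-named genes are left out. Per list described it adds up to 4 members with the lowest p and every called member that moved against the list. The text prints only some of the members that the last part allows, and that choice was made after their values were seen. Gene positions are from GENCODE vM21 on GRCm38 (mm10), matched by symbol or synonym, and 378 of the gene rows had no match.

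The edgeR steps were tested on simulated counts for WT paused against WT FBS cells with 200 changed genes, where 15004 genes were tested. Of genes changed 2-fold, 98% of those raised and 96% of those lowered were recovered, and 100% of those changed 4-fold in either direction. Of 206 calls, 4.37% were false. All simulated genes had a dispersion of 0.02, no library stood apart, and the changed genes were not drawn from the lowest counts. In the real data WT FBS replicate 1 stood apart, so these shares do not carry over to the real comparison. Total counts per sample ranged from 10615548 to 39566713, with 1.058 to 3.328% of counts in ERCC rows. Replicates were compared before averaging, and no pair agreed within sampling noise (lowest chi-square per degree of freedom 5.13). The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Rn45s, the ribosomal RNA precursor, took 12.857 to 28.012% of gene counts, with the highest share in replicate 1 of every group.

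The alternatives tried were ERCC totals alone, low-abundance ERCC rows, TMM or median-ratio scaling over genes, DESeq2 1.42.0, and limma on the deposited log2 values. Others were other filters on low counts, the replicate number as a block, fits of 2 groups only, and leaving out each sample in turn. Leaving out all replicate 1 libraries, leaving out genes of chromosomes 1, 8 and Y or 1, 3, 8, 11 and Y, RNA per cell without Rn45s and Lars2 and RNA per cell of the typical gene were added after seeing the data. RNA per cell without mitochondrial-encoded genes gave no value of its own, since the count table used here held none. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.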

Results

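The series holds polyadenylated RNA counts of 12 samples of E14 mouse embryonic stem cells, 3 in each of 4 groups: WT FBS, KO FBS, WT paused and KO paused. Paused cells had been held for 2 weeks with the mTOR inhibitor INK128, a treatment that brings embryonic stem cells into a dormant state resembling embryonic diapause. The design asks how pausing changes RNA in WT cells and in cells without Mettl3, how the genotypes differ in each condition, and whether both genotypes respond to pausing alike. Total counts of replicates 1, 2 and 3 were 12027770, 39566713 and 30643409 in WT FBS, 24978409, 26716469 and 28705195 in KO FBS, 11988239, 10615548 and 22780103 in WT paused, and 20670968, 19501717 and 29793338 in KO paused. Mettl3 (chromosome 14, 52294841 to 52305128, minus strand) stood at 33.9 ± 3.17 CPM in WT FBS, 27.2 ± 1.61 in KO FBS, 35.9 ± 2.85 in WT paused and 30.1 ± 1.31 in KO paused cells (SD, n = 3 each). The labels do not give the part of the gene that was targeted, and counts over the whole gene do not separate an edited message from an intact one, so these levels check the genotype labels only weakly. The Y-linked genes Kdm5d, Ddx3y, Uty and Eif2s3y split the libraries fully by genotype, with 593 to 3124 counts per gene in each of the 6 KO libraries and 0 to 7 in each of the 6 WT libraries.

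Mean RNA per cell was lower in paused than in FBS cells of both genotypes, but no comparison passed the threshold. The ratio of cellular to ERCC counts was 73.4 ± 1.15 in WT FBS and 33.0 ± 4.19 in WT paused cells, and 68.5 ± 23.3 in KO FBS and 38.3 ± 1.9 in KO paused cells (SD, n = 3 each). In WT cells pausing left 0.447 of the RNA (log2 −1.16 ± 0.11 SE) and in KO cells 0.581 (−0.78 ± 0.29). Each pausing comparison had an exact two-sided permutation p of 0.1, the smallest that 3 samples against 3 allow, and an adjusted p of 0.25 over the family of 5. KO and WT cells were not shown to differ in FBS (log2 −0.16 ± 0.28, exact permutation p = 0.7, adjusted 0.7) or when paused (0.22 ± 0.11, exact permutation p = 0.2, adjusted 0.3). The pausing effect in KO minus that in WT was 0.38 ± 0.30 with an exact permutation p of 0.24 (adjusted 0.3), so a smaller loss of RNA in KO cells was not shown. The KO FBS libraries spread from 47.5 in replicate 1 to 93.5 in replicate 2. Without replicate 1 the KO pausing effect was −1.02, the genotype difference in FBS 0.08 and the difference of both pausing effects 0.14. These were −0.53, −0.41 and 0.63 without replicate 2. With Rn45s and Lars2 left out of the cellular counts, the KO pausing effect was −0.71 ± 0.36 (exact permutation p = 0.2). KO FBS replicate 1, at a ratio of 32.99, then lay below KO paused replicate 2, at 34.43.

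**Figure D1:**
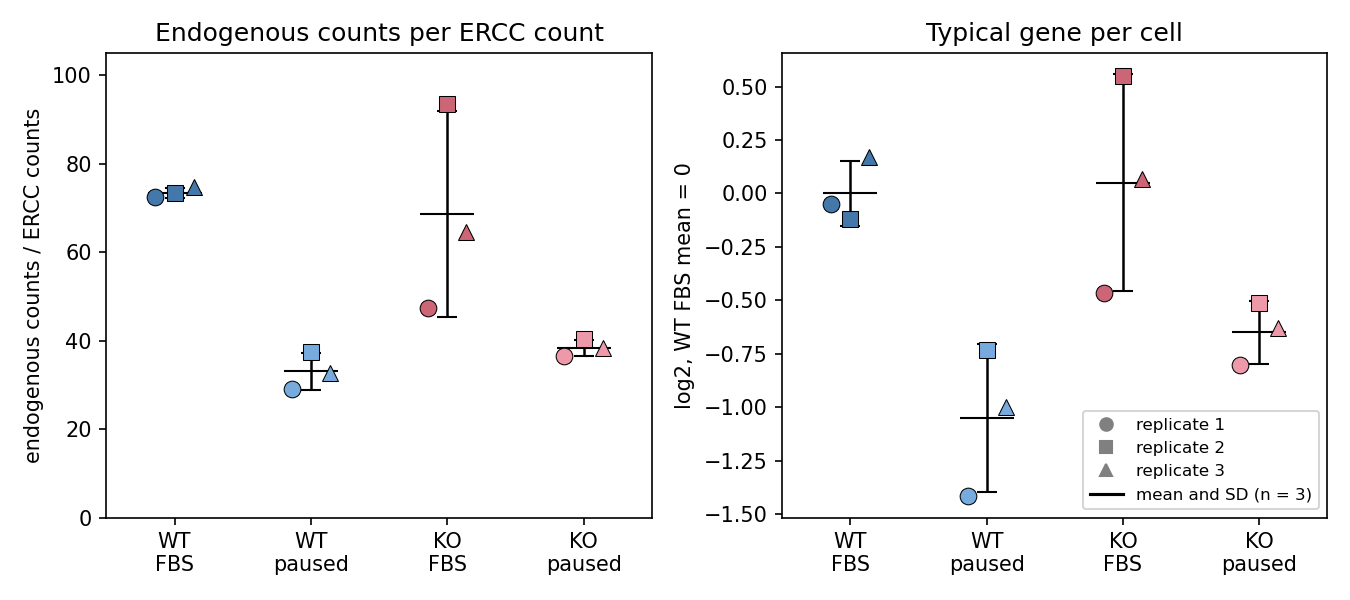
RNA per cell in the 4 groups, with the ratio of cellular to ERCC counts on the left and the level of the typical gene per cell (log2, mean of WT FBS at 0) on the right. Markers are the 3 replicates and lines with bars are the mean and SD. Paused libraries lie between 29.0 and 40.3 on the left, below all FBS libraries, of which KO FBS spans 47.5 to 93.5.

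The question put to WT cells was what mTOR inhibition does to their transcriptome. Mettl3 was not called relative to the typical gene (log2 0.08 ± 0.10, edgeR adjusted p = 0.556). Per cell it was lower (−0.93, adjusted p = 0.00795), as was the median gene (−1.05). Scd1, the desaturase that makes oleic acid, went from 70.5 ± 13.9 to 9.56 ± 0.544 CPM (log2 −2.88 ± 0.14), and Psat1, an enzyme of serine synthesis, from 330 ± 135 to 51.7 ± 4.25 CPM (−2.67 ± 0.24). Prdm14, a repressor that protects naive pluripotency, rose from 21.8 ± 4.21 to 50.8 ± 3.5 CPM relative to the typical gene (1.23 ± 0.14). Per cell it was not called (0.19, edgeR adjusted p = 0.609). Nanog went from 220 ± 44.9 to 415 ± 5.05 CPM, a rise relative to the typical gene (0.91 ± 0.13, edgeR adjusted p = 0.000271) that was not seen per cell, where its log2 value was −0.12. Pou5f1, which encodes Oct4, was not called relative to the typical gene, at 835 ± 209 and 824 ± 73.9 CPM (−0.02 ± 0.17). Mettl14, the partner of Mettl3 in the methyltransferase, fell (−0.40 ± 0.08, edgeR adjusted p = 0.0023), as did Eif4ebp1, the translation repressor controlled by mTOR (−1.01 ± 0.21, adjusted p = 0.00302). Mycn (0.40), Sox2 (0.33) and Myc (−0.01) were not called, although Myc was called without WT FBS replicate 1 (−0.42, edgeR adjusted p = 0.000599). Per cell Pou5f1 (−1.04, edgeR adjusted p = 0.00419), Myc (−1.01, adjusted p = 0.00344) and Sox2 (−0.70, adjusted p = 0.0492) were called lower, where the median gene was at −1.05.

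The highest called genes in paused WT cells were Dock10 (chromosome 1, 80501073 to 80758527), at 1.63 ± 1.43 CPM in FBS and 23.1 ± 4.55 when paused (log2 4.13 ± 0.39, edgeR adjusted p = 1.61e-05), and the polysialyltransferase gene St8sia2 (4.02 ± 0.26). Trim67 (3.86), the sodium leak channel gene Nalcn (3.73), the polarity gene Pard3b (3.72) and Lrrn2 (3.25) followed. Amot (X, 145446425 to 145505181), which encodes the Yap-binding protein angiomotin, fell from 15.2 ± 2.39 to 1.01 ± 0.221 CPM (−3.85 ± 0.21, edgeR adjusted p = 5e-07). Also among the lowest were Mthfd2 of mitochondrial folate metabolism (−3.29 ± 0.42, or −2.68 without WT FBS replicate 3), the endoderm regulator Gata6 (−3.29 ± 0.32), the endocytic receptor gene Cubn (−3.28 ± 0.46, or −4.48 without WT paused replicate 3) and Lef1 (−3.24 ± 0.62). The water and glycerol channel gene Aqp3 had the lowest fitted value (−4.28 ± 0.92), but WT FBS replicate 1 held 212 CPM against 15.4 and 15.5 in the other WT FBS libraries, and without it the value was −1.92. The value of Dock10 was 4.81 without that library.

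Targets of Atf4, the transcription factor of the amino acid response, were lower as a list. Of 34 tested members 0 rose, 31 fell and 3 were not called (0 and 31 adjusted over the list alone), with Phgdh at −2.04 ± 0.25 and Gars at −1.17 ± 0.13. The camera adjusted p was 2.1e-11, and adjusted p = 0.542 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had 0 risen, 33 fallen and 25 not called of 58 (0 and 43 adjusted over the list alone; 57 fallen without WT FBS replicate 1), among them Atp5c1 (−0.82 ± 0.13) and Sdhd (−0.81 ± 0.11). For these camera gave an adjusted p of 1.82e-07, and adjusted p = 0.565 with an estimated correlation. In the translation factor list 26 of 37 fell, such as Eif1 (−0.70 ± 0.07) and Eif3c (−0.52 ± 0.09), 9 were not called and 2 rose (2 and 28 adjusted over the list alone). The camera test gave an adjusted p of 4e-06 (adjusted p = 0.546 with an estimated correlation). The risers were Pdcd4, a translation repressor degraded downstream of mTOR (1.08 ± 0.23; 0.05 per cell, not called), and Eef2 (0.29 ± 0.10, edgeR adjusted p = 0.0348). Eef2 was at −0.72 per cell and lost its call without WT FBS replicate 2 or 3 or WT paused replicate 2 (0.20) or 3. Fatty acid synthesis had 8 of 12 fallen, none risen and 4 not called (0 and 9 adjusted over the list alone), with Fads2 at −1.83 ± 0.18 and Acaca at −1.27 ± 0.11. Tested with camera, the list had an adjusted p of 5.1e-05 (adjusted p = 0.542 with an estimated correlation). Cholesterol synthesis and uptake had 18 of 25 fallen, none risen and 7 not called (0 and 19 adjusted over the list alone), with Cyp51 at −0.85 ± 0.16 and Insig1 at −0.74 ± 0.13. By camera this list had an adjusted p of 0.000121 (adjusted p = 0.546 with an estimated correlation). Growth genes activated by Myc had 20 of 30 fallen and none risen (0 and 22 adjusted over the list alone), among them Ldha (−2.30 ± 0.29), Nme2 (−0.90 ± 0.14) and Npm1 (−0.67 ± 0.14). As a list it had a camera adjusted p of 9.05e-05 (adjusted p = 0.588 with an estimated correlation). WT FBS replicate 1 stood apart, with a median over the Myc-activated list of −0.91 against the other WT FBS libraries, and without it 29 of the 30 fell.

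Glycolysis genes fell in 13 of 21 cases, rose in 2 and were not called in 6 (3 and 13 adjusted over the list alone), with Pgk1 at −1.70 ± 0.16 and Pfkp at −1.35 ± 0.17. Against all other genes camera gave an adjusted p of 0.000711 (adjusted p = 0.546 with an estimated correlation). Ldhb, the lactate dehydrogenase subunit of oxidative tissues, rose relative to the typical gene (0.92 ± 0.22; −0.09 per cell), as did Hk2 (0.50 ± 0.18, edgeR adjusted p = 0.0427; −0.54 per cell), which lost its call without WT paused replicate 1, 2 or 3 (0.44 to 0.53). Extraembryonic endoderm markers fell in 15 of 16 cases with 1 riser (1 and 15 adjusted over the list alone) and a median of −2.13, or −2.01 with members near 0 counts at their bound. Their camera adjusted p was 1.94e-07, and adjusted p = 0.253 with an estimated correlation. Gata4 was at −2.12 ± 0.24 and Col4a1 at −1.36 ± 0.16. The riser was Lamb1 (0.31 ± 0.10, edgeR adjusted p = 0.0286; −0.73 per cell), which lost its call without WT FBS replicate 2 or WT paused replicate 1, 2 or 3 (adjusted p = 0.0629 to 0.0851). Naive and general pluripotency genes had 9 risen, 2 fallen and 13 not called of 24 relative to the typical gene (10 and 2 adjusted over the list alone; 14 risen without WT FBS replicate 1). Per cell 0 rose and 13 fell. The camera test gave an adjusted p of 0.0217 (adjusted p = 0.542 with an estimated correlation). Tcl1 was at 0.87 ± 0.14 (−0.17 per cell), while Dppa5a (−1.63 ± 0.20) and Dppa3 (−2.04 ± 0.40, or −2.88 without WT paused replicate 3) fell. Feedback genes of PI3K and FoxO signalling missed the threshold as a list (6 of 15 risen and none fallen relative to the typical gene, 1 risen and 6 fallen per cell; camera adjusted p = 0.0598, and 0.00136 without WT FBS replicate 1, adjusted p = 0.546 with an estimated correlation). The adaptor gene Irs1 was higher (2.38 ± 0.43, or 3.20 without WT FBS replicate 1). The receptor genes Insr (1.28 ± 0.22) and Igf1r (1.15 ± 0.20) were higher only relative to the typical gene and not called per cell (0.24, adjusted p = 0.5, and 0.12, adjusted p = 0.739).

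Of the other called lists in this comparison, ribosome biogenesis, DNA replication, RNA polymerase II, ribosomal protein, fibroblast, G2/M, trophoblast and p53 target genes all had lower medians, with camera adjusted p from 9.05e-05 to 0.0479, and the trophoblast list was at 0.0827 without WT FBS replicate 1. None of the 17 called lists held with an estimated correlation. Without genes of chromosomes 1, 3, 8, 11 and Y the naive (0.099), p53 target (0.143) and fibroblast (0.064) lists were not called. Relative to the typical gene 2744 genes rose and 3088 fell (47.1% of calls higher), whereas per cell 176 rose and 10512 fell (1.65% higher). The median of all genes was −1.05 on the per-cell scale, so genes between 0 and this shift change direction between scales. Tested over libraries as the typical gene, the shift (−1.05 ± 0.22 SE) had an exact permutation p of 0.1. The per-cell counts largely restate it. Without WT FBS replicate 1, which differed over 2-fold from the mean of the other WT FBS libraries at 2541 genes, 9145 of the genes tested both ways were called relative to the typical gene, 5769 of them among the 5832 called with it.

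**Figure D2:**
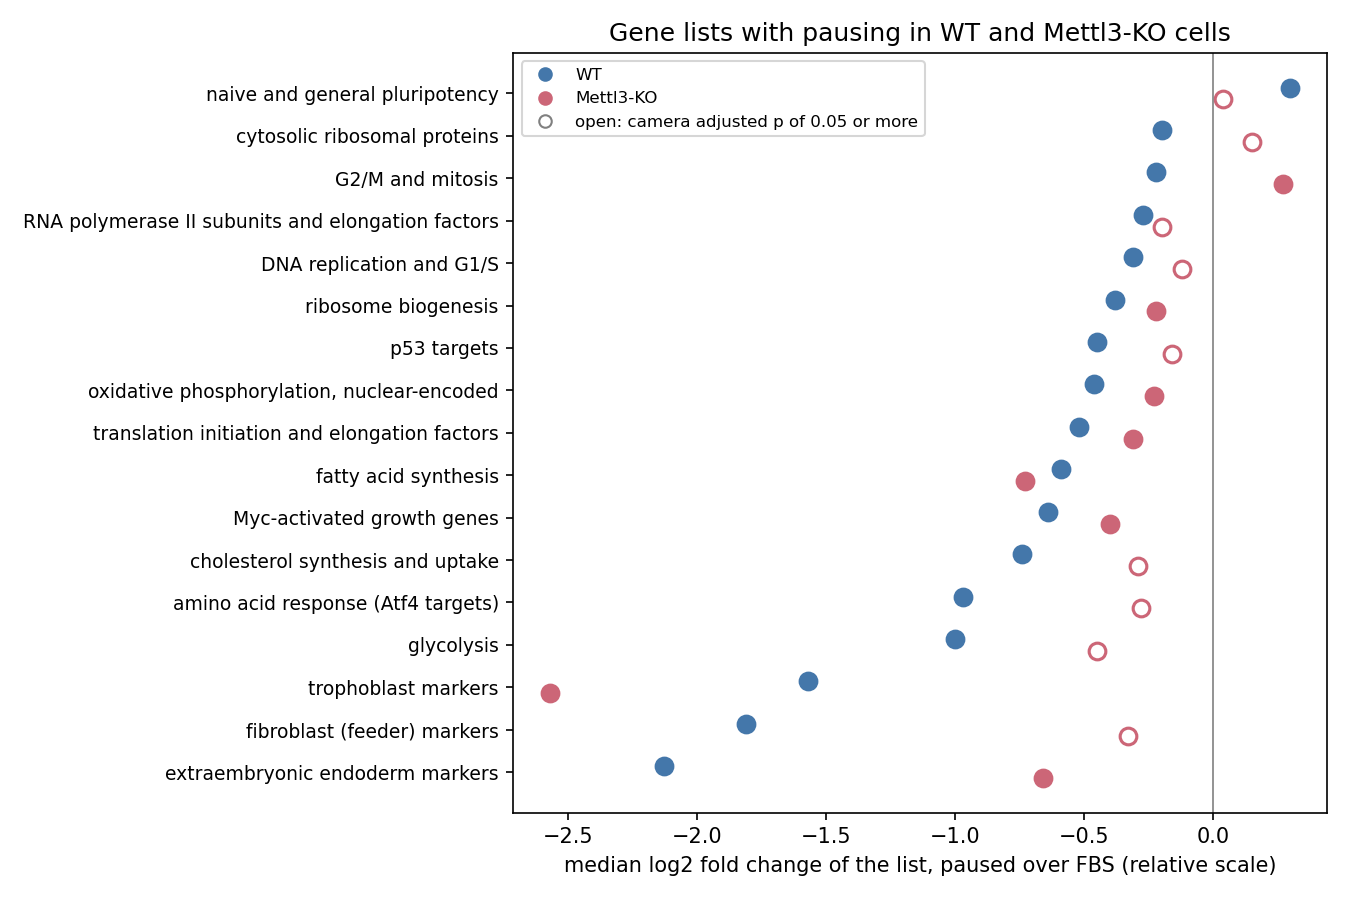
Median log2 fold change of each gene list, paused over FBS and relative to the typical gene, in WT cells (blue) and KO cells (red) for lists called in at least one of them. Open markers have a camera adjusted p of 0.05 or more. Atf4 targets lie at −0.97 in WT and −0.28 in KO cells, and G2/M genes at −0.22 and 0.27, where the KO value is −0.48 per cell.

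In KO cells the same comparison asks what pausing does without the methyltransferase. Mettl3 was at 0.15 ± 0.10 (edgeR adjusted p = 0.246). Markers of trophoblast fell. Krt8 went from 93.1 ± 21.6 to 15.7 ± 1.48 CPM (log2 −2.57 ± 0.21) and Gata3, a regulator of trophectoderm, from 8.34 ± 1.54 to 0.958 ± 0.302 CPM (−3.16 ± 0.26). Sox1 (chromosome 8, 12395295 to 12400126), a transcription factor of neural progenitors, rose from 0.603 ± 0.214 to 17.8 ± 6.01 CPM (4.88 ± 0.33, edgeR adjusted p = 6.58e-07). Nanog fell (−0.40 ± 0.13, edgeR adjusted p = 0.0239), a call that was lost without KO FBS replicate 2 (−0.42) or 3 (−0.33) or KO paused replicate 1 or 3 (−0.38 each). Mettl14 rose relative to the typical gene (0.68 ± 0.08, edgeR adjusted p = 3.28e-05) but was at −0.06 per cell. Its 49 neighbours on chromosome 3 rose as well, at a median of 0.41. Sox2 likewise rose only relative to the typical gene (0.50 ± 0.14, edgeR adjusted p = 0.0143; −0.27 per cell), and its call was lost without KO FBS replicate 1 (0.44) or KO paused replicate 3 (0.43). Pou5f1 (−0.19), Mycn (0.37), Myc (0.02) and Eif4ebp1 (−0.38) were not called relative to the typical gene. Per cell Pou5f1 (−0.97, edgeR adjusted p = 0.0121), Myc (−0.75, adjusted p = 0.0399) and Eif4ebp1 (−1.14, adjusted p = 0.00185) were called lower, where the median gene was at −0.715.

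Beside Sox1, the highest genes were the forebrain homeobox genes Gsx1 (4.41 ± 0.53) and Six3 (3.73 ± 0.27), the growth factor genes Fgf1 (4.26 ± 0.28) and Fgf18 (3.75 ± 0.24), and Casq2 (3.72 ± 0.16), whose 49 neighbours on chromosome 3 had a median of 0.99. Plac8 (chromosome 5, 100553725 to 100572245) was 85.7-fold lower in paused KO cells, with a counting interval of 44.9 to 188, at 9 counts over the 3 paused libraries. Calcoco2, an autophagy receptor gene, went from 91.8 ± 9.2 to 1.67 ± 0.33 CPM (−5.78 ± 0.28, edgeR adjusted p = 6.15e-08). Vrtn (−5.39), Acpp (−5.33), Slfn9 (−5.00) and Slc4a5 (−4.99) were the next lowest.

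All 9 tested trophoblast markers fell in paused KO cells (0 and 9 adjusted over the list alone), with Krt7 at −3.81 ± 0.30 and Krt18 at −3.15 ± 0.26, and this list held under both settings (camera adjusted p = 4.19e-05; adjusted p = 0.0484 with an estimated correlation). Genes of G2/M and mitosis rose relative to the typical gene in 21 of 38 cases, with 1 fallen and 16 not called (22 and 1 adjusted over the list alone), whereas per cell 0 rose and 6 fell. Their camera adjusted p was 0.000604, and adjusted p = 0.599 with an estimated correlation. The phosphatase gene Cdc25b (1.21 ± 0.14; 0.43 per cell, not called) and Cenpf (0.84 ± 0.10; 0.09 per cell, not called) were among them, as were Cdc25c (0.64 ± 0.09; −0.11 per cell) and Cenpa (0.54 ± 0.08; −0.22 per cell). Birc5 fell (−0.24 ± 0.07, edgeR adjusted p = 0.0204) but lost its call without KO FBS replicate 2 or 3 or any 1 of the KO paused replicates (−0.25 to −0.21, adjusted p = 0.0507 to 0.0791). Its 49 neighbours on chromosome 11 had a median of −0.36, and those of Acaca, a fatty acid synthesis gene, −0.46. Fatty acid synthesis genes had 7 of 12 fallen, 1 risen and 4 not called (1 and 7 adjusted over the list alone). Tested with camera, the list had an adjusted p of 0.021 (adjusted p = 0.92 with an estimated correlation). Acss2 was at −1.78 ± 0.17, Scd1 at −1.59 ± 0.13 and Acaca at −1.06 ± 0.11, and the riser was the desaturase gene Fads1 (0.56 ± 0.11; −0.19 per cell). Of the Myc-activated genes 10 of 30 fell, 2 rose and 18 were not called (2 and 10 adjusted over the list alone; 22 fallen without WT FBS replicate 1), with Ldha at −2.48 ± 0.29 and Hspe1 at −1.50 ± 0.24, whose 49 neighbours on chromosome 1 had a median of −1.27. By camera this list had an adjusted p of 0.0143 (adjusted p = 0.92 with an estimated correlation). The risers were the cyclin gene Ccnd2 (2.74 ± 0.54) and Cdk4 (0.32 ± 0.11, edgeR adjusted p = 0.0374; −0.45 per cell), which lost its call without KO FBS replicate 1 (0.25) or 2 or KO paused replicate 2 or 3 (adjusted p = 0.0848 to 0.138).

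Neural markers missed the threshold as a list (8 risen, 2 fallen and 2 not called of 12; 8 and 3 adjusted over the list alone; 2 risen and 3 fallen per cell; camera adjusted p = 0.0957; adjusted p = 0.92 with an estimated correlation). Tubb3 (1.19 ± 0.20) and Elavl3 (1.09 ± 0.15) rose relative to the typical gene and were not called per cell (0.40, adjusted p = 0.277, and 0.31, adjusted p = 0.425). Neurog1 (−2.16 ± 0.31) and Nes (−0.94 ± 0.28, edgeR adjusted p = 0.0187) fell. Nes lost its call without KO FBS replicate 3 or KO paused replicate 1, 2 or 3 (−0.96 to −0.91, adjusted p = 0.0507 to 0.0616). Translation factor, oxidative phosphorylation, ribosome biogenesis and extraembryonic endoderm lists also had lower medians (camera adjusted p from 0.0143 to 0.0498; adjusted p = 0.92 each with an estimated correlation). Atf4 targets, with 3 risen and 10 fallen of 34, missed the threshold (camera adjusted p = 0.0582; adjusted p = 0.92 with an estimated correlation). They passed it without WT FBS replicate 1 (0.0218, with 16 fallen) or all replicate 1 libraries (0.0213). Without genes of chromosomes 1, 3, 8, 11 and Y the fatty acid synthesis (0.0846), Myc-activated (0.0915) and ribosome biogenesis (0.111) lists were not called. In all, 3553 genes rose and 2965 fell relative to the typical gene (54.5% of calls higher), against 375 and 6985 per cell (5.1% higher), where the median of all genes was −0.71. Of the called genes 1464 rose and 1339 fell in both genotypes, against 638 and 599.2 for independent lists, and 344 moved in opposite directions. The fold changes of both genotypes had a Pearson r of 0.476 across genes, which are not independent replicates.

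In FBS the comparison of KO with WT cells asks what the loss of Mettl3 changes in growing cells. KO and WT libraries also differed at Y-linked genes and on chromosomes 1 and 8, so genotype differences cannot be assigned to Mettl3 alone. Mettl3 itself was 1.25-fold lower (log2 −0.32 ± 0.10, edgeR adjusted p = 0.0134), a call lost without KO FBS replicate 1 (−0.28) or WT FBS replicate 2 (−0.24). Mettl14 fell from 40.4 ± 2.7 to 25 ± 0.631 CPM (−0.69 ± 0.08, edgeR adjusted p = 1.22e-05). Pou5f1 fell from 835 ± 209 to 495 ± 67.8 CPM (−0.76 ± 0.17, edgeR adjusted p = 0.0019), while Mycn rose from 158 ± 53.3 to 295 ± 37.7 CPM (0.90 ± 0.20, adjusted p = 0.00192). Per cell Mettl3 (−0.20, edgeR adjusted p = 0.7), Mettl14 (−0.59, adjusted p = 0.161) and Pou5f1 (−0.63, adjusted p = 0.149) were not called. The keratin gene Krt8 went from 8.3 ± 2.64 to 93.1 ± 21.6 CPM (3.53 ± 0.23). Nanog (0.07), Sox2 (−0.10), Myc (−0.84) and Eif4ebp1 (−0.17) were not called, but without WT FBS replicate 1 Sox2 (−0.25), Myc (−1.21) and Eif4ebp1 (−0.40) were.

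Of the 6 highest genes 4 lie on the Y chromosome: Eif2s3y (1010543 to 1028847), Uty (1096861 to 1245759), Ddx3y (1260771 to 1286629) and Kdm5d (897788 to 956786). They were 913-fold (counting interval 356 to 3350), 797-fold (272 to 3870), 583-fold (307 to 1280) and 485-fold (189 to 1780) higher, on 4, 3, 9 and 4 counts over the WT FBS libraries. The mucin gene Muc19 was 537-fold higher on 1 WT count (counting interval 96.1 to 21300), and Olig2, a transcription factor of motor neuron and oligodendrocyte progenitors, 276-fold (127 to 753) on 6. The fitted log2 values of such genes move with single WT libraries. Without WT FBS replicate 1 they were 10.41 for Eif2s3y and 9.50 for Kdm5d, without replicate 2 they were 8.81 for Eif2s3y, 8.40 for Ddx3y and 10.29 for Muc19, and without replicate 3 they were 10.21 for Uty and 10.47 for Ddx3y, against 9.67, 8.77, 9.12, 8.57 and 9.47 for Eif2s3y, Kdm5d, Ddx3y, Muc19 and Uty with all libraries. The lowest was the homeobox gene Nkx6-3 (chromosome 8, 23153269 to 23158948), from 30.9 ± 11.6 to 0.23 ± 0.147 CPM (log2 −7.09 ± 0.41, edgeR adjusted p = 7.57e-08). Klf12 (chromosome 14, 99870632 to 100284679) went from 85.6 ± 50.2 to 2.4 ± 0.231 CPM (−5.15 ± 0.35, or −4.55 without WT FBS replicate 1) and Sox1 from 17.3 ± 4.73 to 0.603 ± 0.214 CPM (−4.85 ± 0.33). For 3 further genes the value rested on WT FBS replicate 1. Trpm1 was at −4.59 ± 1.19 with it and −1.91 without it (−5.23 without WT FBS replicate 2), and the cell death gene Hrk at −4.57 ± 0.93 and −2.42. Kctd19 was 33.8-fold lower (counting interval 15.3 to 93.4, 6 counts in KO FBS), with a fitted log2 value of −5.78, −2.77 without WT FBS replicate 1 and −6.41 without replicate 2 or 3.

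Genes of DNA replication and G1/S were lower in KO cells, with 31 of 38 fallen, 2 risen and 5 not called (2 and 33 adjusted over the list alone), and 1 higher and 14 lower per cell. As a list it had a camera adjusted p of 1.03e-06 (adjusted p = 0.7 with an estimated correlation). The helicase subunit gene Mcm6 was at −1.70 ± 0.09, the licensing factor gene Cdt1 at −1.57 ± 0.11 and Gins4 at −1.19 ± 0.09, while Tk1 (1.12 ± 0.16) and Dbf4 (0.31 ± 0.07) rose. Cytosolic ribosomal protein genes had 51 of 78 fallen, 2 risen and 25 not called (2 and 53 adjusted over the list alone), with Rpl37a at −0.89 ± 0.12 and Rpl32 at −0.85 ± 0.11. Against all other genes camera gave an adjusted p of 2.74e-06 (adjusted p = 0.882 with an estimated correlation). The risers Rpl38 (0.33 ± 0.13, edgeR adjusted p = 0.047) and Rpl23 (0.28 ± 0.11, adjusted p = 0.0442) each lost the call without KO FBS replicate 2 (adjusted p = 0.104 and 0.101) or 3 (0.161 and 0.141), Rpl23 also without a filter on low counts (0.0514), and ribosomal protein genes have many near-identical copies. G2/M and mitosis genes had 26 of 38 fallen, 2 risen and 10 not called (2 and 26 adjusted over the list alone). The camera test gave an adjusted p of 1.22e-05 (adjusted p = 0.2 with an estimated correlation). Nusap1 was at −1.16 ± 0.10, Ccnb2 at −0.78 ± 0.08 and Plk1, the mitotic kinase gene, at −0.77 ± 0.08, against Cdc25b (0.59 ± 0.14) and Birc5 (0.31 ± 0.07), which rose. Atf4 targets had 25 of 34 fallen, 1 risen and 8 not called (1 and 25 adjusted over the list alone), with the cationic amino acid transporter gene Slc7a1 at −2.31 ± 0.20, Atf5 at −1.91 ± 0.14 and Eprs at −1.22 ± 0.10, and Slc38a2 risen (0.53 ± 0.13). Tested with camera, the list had an adjusted p of 0.000153 (adjusted p = 0.882 with an estimated correlation). In the mRNA decay list 18 of 34 fell, 1 rose and 15 were not called (1 and 18 adjusted over the list alone). Among them were the exosome genes Dis3 (−1.36 ± 0.09) and Exosc10 (−0.95 ± 0.08), the deadenylase scaffold gene Cnot1 (−0.81 ± 0.08) and the riser Cnot6l (0.79 ± 0.11). By camera this list had an adjusted p of 0.00191 (adjusted p = 0.146 with an estimated correlation). Per cell few members of these lists were called: 0 higher and 2 lower for ribosomal proteins, 0 and 3 for G2/M and 1 and 3 for mRNA decay, against 0 and 18 for Atf4 targets. Of the genes named from these lists Rpl37a, Rpl32, Rpl38, Rpl23, Ccnb2, Plk1, Cdc25b, Birc5, Dbf4, Slc38a2 and Cnot1 were not called per cell (adjusted p = 0.0604 to 0.405). The 49 neighbours of Rpl23, Rpl38 and Birc5 on chromosome 11 had medians of 0.34, 0.61 and 0.31.

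Of the markers of other cell types, the trophoblast and fibroblast lists were called, and the neural (camera adjusted p = 0.267), mesendoderm (0.341) and extraembryonic endoderm (0.615) lists were not. Trophoblast markers were higher in KO FBS cells in 7 of 9 cases with none lower and 2 not called (7 and 0 adjusted over the list alone), with Krt7 at 4.36 ± 0.32 and Gata3 at 3.75 ± 0.29. As a list it had a camera adjusted p of 0.00191 (adjusted p = 0.146 with an estimated correlation). Fibroblast markers were higher in 10 of 13 cases, lower in 2 and not called in 1 (10 and 2 adjusted over the list alone). Against all other genes camera gave an adjusted p of 0.00338 (adjusted p = 0.7 with an estimated correlation). Col3a1 was at 3.62 ± 0.25 and Col6a1 20.9-fold higher (counting interval 10.8 to 46.3), while Vim (−0.92 ± 0.20) and Pdgfrb (−0.76 ± 0.21; −0.69 per cell, not called) were lower. Translation factor, lysosome, ribosome biogenesis and oxidative phosphorylation lists also had lower medians (camera adjusted p from 0.0078 to 0.0444; adjusted p = 0.882 each with an estimated correlation), of which the lysosome list had an adjusted p of 0.512 without WT FBS replicate 1. Chromosomes 1 and 8 had lower medians in KO cells, −0.28 and −0.46 against −0.15 to 0.18 on the other autosomes, with 12 of 17 windows of 50 genes low on chromosome 1 and 12 of 15 on chromosome 8. Without genes of chromosomes 1, 8 and Y the lysosome (camera adjusted p = 0.0577) and oxidative phosphorylation (0.11) lists were no longer called, and DNA replication (6.35e-05), G2/M (1.38e-05) and Atf4 targets (0.000129) were. In all, 4343 genes were higher and 4492 lower relative to the typical gene (49.2% of calls higher) and 2917 and 1499 per cell (66.1% higher), where the median of all genes was 0.05. Without WT FBS replicate 1, 10547 of the genes tested both ways were called, 8571 of them among the 8835 called with it.

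**Figure D3:**
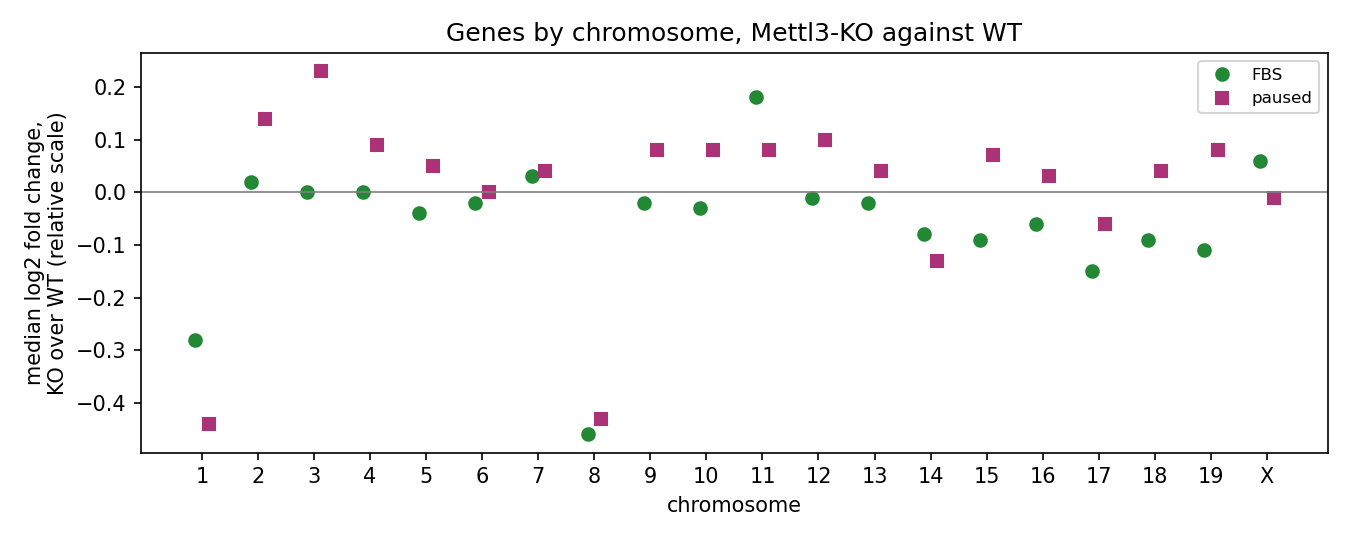
Median log2 fold change, KO over WT and relative to the typical gene, of the tested genes of each autosome and the X chromosome, in FBS (circles) and paused cells (squares). Chromosome 1 lies at −0.28 and −0.44 and chromosome 8 at −0.46 and −0.43, below all other autosomes.

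Among paused cells the comparison asks how KO and WT cells differ in the dormant state. Mettl3 was 1.19-fold lower in KO cells (log2 −0.25 ± 0.10, edgeR adjusted p = 0.0467), at the edge of the threshold: the per-cell value was 0.12, and the call was lost without any 1 of the 6 paused libraries (−0.29 to −0.19, adjusted p = 0.0505 to 0.173) and without a filter on low counts (0.0741). Nanog stood at 176 ± 7.82 CPM against 415 ± 5.05 in WT (−1.24 ± 0.13, edgeR adjusted p = 7.28e-06), Pou5f1 at 434 ± 27.7 against 824 ± 73.9 CPM (−0.92 ± 0.17, adjusted p = 0.000547), and Tbx3 (chromosome 5, 119670669 to 119684724) at 2.78 ± 0.77 against 180 ± 11.7 CPM (−6.05 ± 0.35, adjusted p = 6.78e-08). Of single neural regulators, Neurod1 was higher at 47.6 ± 4.12 against 0.985 ± 0.168 CPM (5.60 ± 0.27) and Pax6 at 20.3 ± 1.68 against 2.23 ± 0.787 CPM (3.27 ± 0.30). The neural list was not called (camera adjusted p = 0.116; adjusted p = 0.916 with an estimated correlation). Mycn (0.87 ± 0.20, edgeR adjusted p = 0.00275) and Mettl14 (0.39 ± 0.08, adjusted p = 0.00136) were higher in KO cells, and Sox2 (0.07), Myc (−0.81) and Eif4ebp1 (0.47) were not called. Myc was near the threshold (edgeR adjusted p = 0.065). It was called with DESeq2 (adjusted p = 0.0358), and by edgeR with a replicate block (0.0499) and without all replicate 1 libraries (1.08e-05). Eif4ebp1 was also called in these edgeR settings (0.0482 and 0.011). The 49 neighbours of Mettl14 on chromosome 3 had a median of 0.71, above its own value. Per cell Pou5f1 (−0.56, edgeR adjusted p = 0.194) and Mettl14 (0.77, adjusted p = 0.0528) were not called, and Eif4ebp1 was called higher (0.84, adjusted p = 0.0293).

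The highest genes were again Y-linked: Kdm5d at 1840-fold (counting interval 330 to 72600), Ddx3y at 1330-fold (455 to 6450), Uty at 1250-fold (428 to 6070) and Eif2s3y at 990-fold (338 to 4800), on 1, 3, 3 and 3 counts over the WT paused libraries. Six3 (chromosome 17, 85613608 to 85629302) had 567 counts in KO and 0 in WT paused cells, at least 109-fold higher with a floor of 3 counts over the group, and Olig2 was 251-fold higher (115 to 685). Fitted log2 values were 12.99 for Kdm5d and 11.27 for Uty without WT paused replicate 1, and 9.64 for Kdm5d and 12.62 for Olig2 without replicate 3, against 10.52, 10.19 and 7.92 for Kdm5d, Uty and Olig2 with all libraries. The lowest were the potassium channel gene Kcnj3 (chromosome 2, 55435970 to 55598145), 170-fold lower (85.7 to 395), Sncg, 73.8-fold lower (37 to 172), and Tbx3, followed by Nkx6-3 (−5.74 ± 0.38), Phf11d (−5.58 ± 0.16) and Skida1 (−5.48 ± 0.46).

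Naive and general pluripotency genes were lower in 15 of 24 cases, higher in 3 and not called in 6 (4 and 16 adjusted over the list alone), and per cell 8 were lower and 4 higher. The camera test gave an adjusted p of 0.00209 (adjusted p = 0.339 with an estimated correlation). Dppa5a was at −3.08 ± 0.22 and Klf5 at −2.71 ± 0.19, while Rex2 (2.95 ± 0.18), Dppa3 (1.98 ± 0.40, or 2.82 without WT paused replicate 3) and Fbxo15 (0.40 ± 0.11) were higher. DNA replication and G1/S genes were lower in 24 of 38 cases, higher in 2 and not called in 12 (2 and 24 adjusted over the list alone), with the polymerase gene Pola1 at −1.57 ± 0.11 and Mcm6 at −1.12 ± 0.09, against Tk1 (0.99) and Dbf4 (0.58), whereas per cell 3 were lower and 2 higher. Tested with camera, the list had an adjusted p of 0.000153 (adjusted p = 0.916 with an estimated correlation). In the mRNA decay list 15 of 34 were lower, 1 higher and 18 not called relative to the typical gene (1 and 15 adjusted over the list alone), whereas per cell 2 were higher and 0 lower. Its camera adjusted p was 0.0207 (adjusted p = 0.339 with an estimated correlation, 0.0665 without genes of chromosomes 1, 8 and Y, and 0.118 without those of 1, 3, 8, 11 and Y), and Zfp36l2 (−1.07 ± 0.08), Cnot1 (−0.97 ± 0.08) and the riser Cnot6l (0.47 ± 0.11) were among its members. Fibroblast markers were higher in 10 of 13 cases, lower in 1 and not called in 2 (11 and 1 adjusted over the list alone). By camera this list had an adjusted p of 0.00176 (adjusted p = 0.691 with an estimated correlation). Tagln was at 2.75 ± 0.29, Acta2 was 285-fold higher (50.8 to 11300) and Col3a1 129-fold (23 to 5130) on 1 WT count each, and Pdgfrb was lower (−1.46 ± 0.24). Fitted values were 10.32 for Acta2 without WT paused replicate 1, and 6.98 for Acta2 and 9.08 for Col3a1 without replicate 3, against 7.85 and 6.70. Targets of p53 missed the threshold as a list (14 higher, 3 lower and 5 not called of 22; camera adjusted p = 0.0567; adjusted p = 0.916 with an estimated correlation). They passed it without WT FBS replicate 1 (0.0106), without all replicate 1 libraries (0.00937) and with ERCC scaling (0.0255). Among them were Ddit4l at 3.15 ± 0.34 and Eda2r at 1.17 ± 0.10, while Pmaip1 (−0.61 ± 0.15), Rrm2b (−0.57 ± 0.13) and Xpc (−0.29 ± 0.10; 0.08 per cell) were lower. The call of Xpc (edgeR adjusted p = 0.0229) was lost without KO paused replicate 1 or 3 or WT paused replicate 2 or 3 (adjusted p = 0.0565 to 0.0956). Of the list members named here Mcm6, Zfp36l2, Cnot1, Pmaip1 and Rrm2b were not called per cell (adjusted p = 0.0671 to 0.724).

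Chromosomes 1 and 8 again had the lowest medians (−0.44 and −0.43), against −0.13 to 0.23 on the other autosomes. In all, 4270 genes were higher and 3647 lower relative to the typical gene (53.9% of calls higher), and 4146 and 859 per cell (82.8% higher), where the median of all genes was 0.39. Of the genotype calls 2920 were higher and 2610 lower in FBS and in paused cells alike, against 1213.6 and 1072.1 for independent lists, with 308 in opposite directions and a Pearson r of 0.734 across genes.

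Whether both genotypes responded alike was tested as the pausing effect in KO minus that in WT. Mettl3 was not called (log2 0.07 ± 0.14, edgeR adjusted p = 0.78). Nanog, which rose in WT and fell in KO cells relative to the typical gene, differed by −1.31 ± 0.18 (edgeR adjusted p = 0.000507), although its per-cell difference of −1.03 was not called (adjusted p = 0.215). Mettl14, which fell in WT and rose in KO cells, differed by 1.08 ± 0.11 (edgeR adjusted p = 7e-05; 1.36 per cell, adjusted p = 0.0566). Its 49 neighbours on chromosome 3 had a median difference of 0.50. The mitotic kinase gene Plk1 went from 163 ± 10.3 to 111 ± 4.49 CPM in WT and from 95.5 ± 2.47 to 116 ± 6.84 CPM in KO cells (0.83 ± 0.11; 1.10 per cell, adjusted p = 0.164). Stc2, which responds to amino acid shortage, went from 7.7 ± 3.17 to 1.8 ± 0.233 CPM in WT and from 4.89 ± 0.825 to 11.3 ± 1.23 CPM in KO cells (edgeR adjusted p = 0.000176). Pou5f1 (−0.17), Mycn (−0.03), Myc (0.03), Sox2 (0.17) and Eif4ebp1 (0.64) were not called, but without WT FBS replicate 1 Myc (0.41), Sox2 (0.33) and Eif4ebp1 (0.88) were.

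Six3 and Acta2 had the highest fitted differences (8.28 and 6.29), which depend on the prior count since WT paused cells held 0 and 1 of their counts, and that of Acta2 was 8.75 without WT paused replicate 1 and 5.39 without replicate 3. Gsx1 went from 2.48 ± 1.91 to 1.27 ± 0.409 CPM in WT and from 0.367 ± 0.0742 to 8.01 ± 1.61 CPM in KO cells (5.61 ± 0.75, edgeR adjusted p = 0.000389). The neural and endocrine regulator Insm1 (4.30 ± 0.48) and the connexin gene Gjb1 (4.26 ± 0.47) followed, with the potassium channel gene Kcna3 (3.90 ± 0.90), whose value was 3.06 and not called (edgeR adjusted p = 0.0992) without WT FBS replicate 3, 5.68 without WT paused replicate 2 and 3.22 without WT paused replicate 3. The 49 neighbours of Kcna3 on chromosome 3 had a median difference of 1.06. Heph (X, 96455359 to 96574485), which encodes a copper-dependent ferroxidase, had the lowest difference, from 1.12 ± 0.0887 to 5.71 ± 1.39 CPM in WT and from 6.89 ± 0.241 to 1.02 ± 0.199 CPM in KO cells (−5.02 ± 0.29, edgeR adjusted p = 2.94e-06). Gata3 (−4.43 ± 0.43), Krt42 (−4.39 ± 0.42), Ccdc141 (−3.69 ± 0.37), the cyclooxygenase gene Ptgs2 (−3.66 ± 0.33) and Calcoco2 (−3.64 ± 0.40) were next.

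G2/M and mitosis genes had a more positive pausing effect in KO than in WT cells in 23 of 38 cases, with 0 more negative and 15 not called (26 and 0 adjusted over the list alone). As a list it had a camera adjusted p of 3.25e-08 (adjusted p = 0.196 with an estimated correlation). Cenpa was at 0.76 ± 0.11 and Ccnb2 at 0.71 ± 0.11, and per cell 0 members were called in either direction, at a median of 0.77. Atf4 targets had 17 of 34 more positive, none more negative and 17 not called (22 and 0 adjusted over the list alone), with Psat1 at 1.86 ± 0.32, Atf5 at 1.18 ± 0.19 and Sars at 1.90 ± 0.19, whose neighbours on chromosome 3 had a median of 1.06. Against all other genes camera gave an adjusted p of 1.69e-06 (adjusted p = 0.872 with an estimated correlation). Extraembryonic endoderm markers had 7 of 16 more positive, none more negative and 9 not called (7 and 1 adjusted over the list alone), with Gata6 at 2.98 ± 0.49 and Col4a1 at 1.83 ± 0.22. The camera test gave an adjusted p of 0.0086 (adjusted p = 0.619 with an estimated correlation). This list was at an adjusted p of 0.0504 without WT FBS replicate 1, 0.067 without all replicate 1 libraries, 0.156 without genes of chromosomes 1 and 8 and 0.106 without those of chromosomes 1, 3, 8, 11 and Y. Trophoblast markers had 4 of 9 more negative, none more positive and 5 not called (0 and 4 adjusted over the list alone), with Krt8 at −1.94 ± 0.32. Tested with camera, the list had an adjusted p of 0.00832 (adjusted p = 0.203 with an estimated correlation, and 0.0521 without all replicate 1 libraries). Oxidative phosphorylation genes had 5 of 58 more positive, none more negative and 53 not called (2 and 0 adjusted over the list alone), with Atp5f1 at 1.87 ± 0.25, whose neighbours on chromosome 3 had a median of 0.81. By camera this list had an adjusted p of 0.0357 (adjusted p = 0.872 with an estimated correlation, 0.0777 without genes of chromosomes 1 and 8, and 0.0906 without those of chromosomes 1, 3, 8, 11 and Y). Ribosomal protein genes had 5 of 78 more positive and none more negative, with 0 in either direction adjusted over the list alone (camera adjusted p = 0.00113; adjusted p = 0.872 with an estimated correlation). Rpl41, one of them (0.56 ± 0.16, edgeR adjusted p = 0.0351), lost its call when any library other than WT FBS replicate 1, KO FBS replicate 3 or WT paused replicate 2 was left out (0.47 to 0.60).

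In all, 1469 genes had a more positive and 1262 a more negative pausing effect in KO cells relative to the typical gene (53.8% of calls more positive), against 464 and 254 per cell (64.6%), where the median of all genes was 0.37. In WT FBS replicate 1 the medians against the other WT FBS libraries were −0.62 over oxidative phosphorylation, −0.55 over Atf4 targets, −0.42 over ribosomal protein and −0.02 over G2/M genes. Without it 6425 of the genes tested both ways were called, 2729 of them among the 2731 called with it, and the counts of more positive members rose to 30 for G2/M, 26 for Atf4 targets, 40 for oxidative phosphorylation and 55 for ribosomal proteins.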

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

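The tests without WT FBS replicate 1, without genes of chromosomes 1, 3, 8 and 11 and of the levels already present in FBS were chosen after the results were seen. Each result here stands out because the test of the difference between both pausing effects, KO minus WT, passed its threshold. Relative to the typical gene 2731 genes passed, and 718 did per cell. Single genes with a more positive effect in KO cells were Six3 (log2 8.28), Acta2 (6.29), Gsx1 (5.61), Insm1 (4.30), Gjb1 (4.26), Kcna3 (3.90) and Mettl14 (1.08). The values of Six3 and Acta2 depend on the prior count because WT paused cells held 0 and 1 of their counts, and Kcna3 was at 3.06 and not called (edgeR adjusted p = 0.0992) without WT FBS replicate 3. Kcna3 and Mettl14 lie in a stretch of chromosome 3 that moved as a whole, where their 49 neighbours had median differences of 1.06 and 0.50. More negative in KO cells were Heph (−5.02), Gata3 (−4.43), Krt42 (−4.39), Ccdc141 (−3.69), Ptgs2 (−3.66), Calcoco2 (−3.64) and Nanog (−1.31). Krt42 and Calcoco2 lie in a stretch of chromosome 11 where 122 of 550 genes were more negative and 8 more positive. Their 49 neighbours there had median differences of −0.22 and −0.31. The lists called by camera had median differences of 1.21 for extraembryonic endoderm markers, 0.92 for Atf4 targets, 0.48 for G2/M, 0.32 for ribosomal proteins, 0.27 for oxidative phosphorylation and −1.23 for trophoblast markers. None of the 6 held with an estimated correlation.

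Genotype labels were exchanged within conditions in 100 of the 200 distinct splits, the real one included. Per cell, 7 of the 100 splits gave as many genes as the real 718 (highest other 6578), so chance was not excluded. Relative to the typical gene, 3 of the 100 gave as many as the real 2731 (highest other 10000), a share under 0.05. Most other splits put KO and WT libraries into the same group. The large difference between the genotypes then widens the spread and can lower the counts, so this share does not measure chance. The split with 6578 and 10000 genes, several times the real counts, exchanged all 3 paused libraries of each genotype and so points to a structure of the samples, the difference between the genotypes itself. In the comparisons of 2 groups the real split was the 1 of 10 with the highest count in each case, and 10 splits are too few for a share under 0.05. Per cell the real counts and the highest others were 10688 and 417 for WT pausing, 7360 and 0 for KO pausing, 4416 and 0 for the genotypes in FBS and 5005 and 0 for the paused genotypes. Relative to the typical gene the real counts were 5832, 6518, 8835 and 7917 in the same order, and the highest other was 0 in each. The other splits mix both groups, which widens the spread, so their low counts say little about chance. At an unadjusted edgeR p under 0.05 the highest others were 3524, 6694, 3344 and 269 genes per cell and 4705, 197, 2759 and 206 relative to the typical gene.

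The pattern followed up was that the G2/M (medians −0.22 in WT and 0.27 in KO cells) and Atf4 target lists (−0.97 and −0.28) had a more positive pausing effect in KO cells relative to the typical gene, called at the preset correlation only (0.196 and 0.872 with an estimated one). At the preset one, genes on chromosomes 1 and 8, or 1, 3, 8 and 11, are argued against. The higher camera adjusted p was 1.75e-06 without genes of chromosomes 1 and 8 and 2.21e-05 without those of chromosomes 3 and 11 as well. Without WT FBS replicate 1 it was 4.49e-08. That library lay at −0.55 over Atf4 targets and −0.02 over G2/M genes against the other WT FBS libraries. It thus worked against the Atf4 pattern and hardly moved G2/M, so leaving it out could not have shown it as the source. A lower level in KO cells already in FBS stays open: relative to the typical gene the median genotype difference was −0.45 for G2/M and −0.93 for Atf4 targets in FBS and −0.02 and −0.03 in paused cells, where the lower ratio of 22.5 rests on a rounded value near 0. Per cell the medians were −0.36 and −0.88 in FBS and 0.36 and 0.35 in paused cells. For each gene the difference of pausing effects is the genotype difference when paused minus that in FBS. The genotype medians therefore restate the pattern and cannot decide its origin. Whether the pattern follows from the loss of Mettl3 or from another difference between these cells was not tested.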

How the results depend on the processing

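Leaving out all replicate 1 libraries together, leaving out genes of chromosomes 1, 8 and Y or 1, 3, 8, 11 and Y, and the measures of RNA per cell for the typical gene and without Rn45s and Lars2 were chosen after the results were seen. The per-cell alternative without mitochondrial-encoded genes was not run, since the count table used here held none. Calls of small changes are limited by the 3 samples per group and by totals as low as 10615548 counts, and per-cell values by the ERCC share of 1.058 to 3.328%. Unless said otherwise the cause of a change was not tested.

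RNA per cell kept its direction under every alternative for the pausing comparisons, the paused genotypes and the difference. The uncalled genotype difference in FBS was 0.05 for the typical gene. With single libraries left out the values ran from −1.25 to −1.07 for WT pausing, −1.02 to −0.53 for KO pausing, −0.41 to 0.08 for the genotypes in FBS, 0.13 to 0.32 for the paused genotypes and 0.14 to 0.63 for the difference.

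Counts of genes per cell moved by over 1.5 times with TMM over genes, which is the relative scale, to 5832 (WT pausing), 8835 (genotypes in FBS), 7917 (paused genotypes) and 2731 (difference). They moved to 4756 for KO pausing with limma on the authors' log values and to 2916 for the genotypes in FBS with only these groups fitted. With single libraries left out they ran from 8105 to 11505, 4112 to 10459, 3300 to 5294, 3608 to 6293 and 397 to 1718, in the order WT pausing, KO pausing, FBS, paused and difference. Relative counts moved to 2769 for WT pausing with only these groups fitted, where the spread comes from the WT libraries alone. The SD of the log2 gap between a library and the others of its group was 0.34 to 0.774 in WT and 0.224 to 0.302 in KO libraries. The fit of 4 groups pools both, so the count of 5832 rests in part on the closer KO libraries. Without all replicate 1 libraries they moved to 8992 for WT pausing and 5746 for the difference. With single libraries left out they ran from 4171 to 9219, 5071 to 9349, 7725 to 10723, 6720 to 10203 and 1819 to 6463, and the highest of each was without WT FBS replicate 1. The main counts are 10688, 7360, 4416, 5005 and 718 per cell and 5832, 6518, 8835, 7917 and 2731 relative to the typical gene. With an estimated correlation the lists called went from 17, 8, 11, 4 and 6 to 0, 1, 0, 0 and 0. With ERCC scaling 18, 6, 8, 6 and 5 lists were called, which need not be the same lists. Without genes of chromosomes 1, 3, 8, 11 and Y KO pausing had 5. Without WT FBS replicate 1 KO pausing had 13 lists and the difference 15, and without all replicate 1 libraries KO pausing had 13, the paused genotypes 7 and the difference 12.

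The replicate numbers are not taken to pair the samples, since 10 and not all of the 18 same-numbered pairs had a correlation of deviations over 0.1 (−0.022 to 0.27). The 6 pairs of replicate 1 did (0.131 or more), and 10 of 12 samples correlated best with their own number, a hint from the data and not the design. With the replicate number as a block the per-cell count for the difference was 1970, and the other counts of genes stayed within 1.5 times. Counts of list members moved more. In the difference 25 ribosomal protein genes were then more positive and 2 more negative, and 9 oxidative phosphorylation genes were more positive and 0 more negative. Fewer members of both lists were called without the block. With it the p53 list of WT pausing was not called (camera adjusted p = 0.0611), the Atf4, glycolysis and RNA polymerase II lists of KO pausing were (0.0395 each), and Sox2 in WT pausing (edgeR adjusted p = 0.0195) and Myc (0.0499) and Eif4ebp1 (0.0482) between the paused genotypes gained the call.

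Of 219 results for named genes, 161 kept direction and call per cell, 36 lost and 8 gained the call, and 14 reversed. The reversals follow the shift of the median gene. In WT pausing they were Nanog (−0.12), Tcl1 (−0.17), Lamb1 (−0.73), Eef2 (−0.72), Hk2 (−0.54) and Ldhb (−0.09). In KO pausing they were Mettl14 (−0.06), Sox2 (−0.27), Cenpa (−0.22), Cdc25c (−0.11), Fads1 (−0.19) and Cdk4 (−0.45), and among the paused genotypes Mettl3 (0.12) and Xpc (0.08). DESeq2 kept 216 results and gained 2, Myc between the genotypes in FBS (DESeq2 adjusted p = 0.0378) and when paused (0.0358). No filter on low counts kept 217 and lost 2, the block kept 216 and gained 3, and leaving out replicate 1 kept 204, gained 14 and lost 1. Over all single libraries left out, 1455 values kept the call, 56 lost and 7 gained it.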

Other observations

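The tests of shared reads between Y and X copies, of stretches of chromosomes 1, 3 and 11, of a property of the replicate 1 libraries and of exon length without loss of Mettl3, and the list tests without WT FBS replicate 1, were chosen after the results were seen. The list results in this paragraph missed the camera threshold with all libraries included. Genes of the m6A machinery were higher in KO FBS cells in 10 of 21 cases, lower in 7 and not called in 4 (10 and 7 adjusted over the list alone), with a median of 0.16 and a camera adjusted p of 0.585 (adjusted p = 0.882 with an estimated correlation). When paused, 9 were higher and 4 lower in KO cells (10 and 5 adjusted over the list alone; camera adjusted p = 0.495). Components of the mTOR pathway, the target of the inhibitor, had 2 risen, 10 fallen and 20 not called of 32 in WT cells on pausing (2 and 10 adjusted over the list alone; camera adjusted p = 0.233). Without WT FBS replicate 1 they had 8 risen and 16 fallen. Neural markers were higher in paused KO than in paused WT cells in 8 of 12 cases and lower in 3 (8 and 3 adjusted over the list alone), at a median of 1.51 and a camera adjusted p of 0.116. Imprinted genes had 10 risen and 5 fallen of 27 with WT pausing relative to the typical gene (10 and 5 adjusted over the list alone; camera adjusted p = 0.0901), where per cell 0 rose and 13 fell. Lysosome and autophagy genes, which are under control of mTOR through Tfeb, had 4 risen and 6 fallen of 53 with WT pausing (3 and 4 adjusted over the list alone; camera adjusted p = 0.829). Without WT FBS replicate 1 they had 29 risen and 8 fallen and an adjusted p of 9.1e-05 at the preset correlation (with an estimated one and all libraries, 0.95).

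KO and WT cells differed by chromosome. Y-linked genes had 593 to 3124 counts per KO library and 0 to 7 per WT library, and reads shared with their X-linked copies are argued against, since the highest Y to X ratio in WT libraries was 0.112% of that in KO libraries. Genes of chromosomes 1 and 8 lay below the other autosomes by −0.27 and −0.45 in FBS and by −0.50 and −0.49 when paused, and a lower expression level of these genes is argued against, since the gap was −0.27 or lower in every class of mean expression. A different copy number of whole chromosomes could not be decided. Of the 32 windows of 50 genes on both chromosomes 75% were low in both conditions (3.6% of 250 on the other autosomes), short of the 80% set beforehand. Chromosome 8 alone reached 80% and chromosome 1 held 70.6%, but the threshold was set for both together. The first 4 windows of chromosome 1 were at −0.04 to 0.42 in FBS and −0.60 to −0.40 when paused, and 2 copies against 3 would give −0.58. These values may mean that the KO and WT cells differ by more than Mettl3, and beyond copy number no biological explanation was tested.

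In 3 stretches of at least 3 neighbouring windows the genotype difference changed by over 0.25 between FBS and paused cells: chromosome 1 (3205901 to 58595964), chromosome 3 (100922202 to 141834924) and chromosome 11 (83582056 to 121161973). Against the other autosomes, KO over WT medians went from 0.29 to −0.45, from 0.06 to 0.81 and from 0.44 to 0.00. Pausing medians in the same order were −0.71, 0.64 and −0.51 in KO cells and −0.02, −0.03 and −0.06 in WT cells. A single library is argued against, since with any 1 left out the difference of pausing effects closest to 0 was −0.44. KO cells in FBS and paused KO cells could differ by more than pausing, and a different copy number of these stretches, or regional regulation, stays open and was not tested.

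WT FBS replicate 1 differed over 2-fold from the mean of the other WT FBS libraries at 2541 genes, with lower medians over formative pluripotency (−1.32) and Myc-activated genes (−0.91) and higher ones over lysosome genes (0.82) and PI3K and FoxO feedback genes (1.02). Its lower depth is argued against, since replicate 2 thinned to its total differed from replicate 3 at 409 genes. On the axis from the other WT FBS (0) to the WT paused libraries (1) it lay at 0.50. A position below 0.6 had been set beforehand as the mark against a paused library under this label. Its ratio of cellular to ERCC counts of 72.4 was that of FBS cells. For a property shared by the replicate 1 libraries the highest squared correlation of its deviation with another of them was 0.0529. No same-numbered pair in the series had a correlation over 0.27, so this test could hardly have shown such a property and does not decide. In every group replicate 1 lay farther from replicates 2 and 3, by chi-square per degree of freedom, than these lay from each other. A culture with a partial response, or a mixture of both states, could give such a position and stays open, and no biological explanation was tested.

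One hypothesis was that messages of genes with a long internal exon, where m6A is known to be dense, are higher without Mettl3. Genes whose longest internal exon has at least 1000 bases (906 genes) had a median log2 fold change, KO over WT, above that of genes with under 200 bases (5327) by 0.31 in FBS and 0.14 when paused. Both gaps had a permutation p of 1e-05, the smallest that 100000 permutations can give, and genes are not independent replicates. Pausing, where the genotype stays the same, gave a gap of 0.31 in WT and 0.16 in KO cells (−0.12 in the class of mean expression where it was lowest), and the pausing effect in KO minus that in WT had a gap of −0.17. The gaps of WT pausing and of the genotypes in FBS share the WT FBS libraries and so are not independent. Without WT FBS replicate 1 each was 0.39. The gaps may therefore reflect methylation or another property tied to exon length, and both stay open.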
